A study of Arabidopsis thaliana with 10 samples.

How the data were processed

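The data are mRNA sequencing libraries of 12-day-old Arabidopsis seedlings, made with a stranded mRNA kit, 10 in all and 2 per group. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.13 to TAIR10 and compared with Cuffdiff 2.2.0; the read trimming, the annotation version and the use of strand in counting are not given in the sources used here. The annotation columns of the deposited tables name the assembly TAIR10.1. The authors deposited 3 tables, BL against mock, BEH2-YFP against Col-0 and BZR1-YFP against Col-0. Per the file headers, each gives the FPKM of both groups, pooled by the authors over the 2 libraries. The test statistic is a score of the authors' Cuffdiff run. The deposited fold change is on the log2 scale, without a pseudocount. The p-value and the q-value are those of the authors' Cuffdiff run; the smallest p-value is 5e-05, reached by 654, 1390 and 132 genes. Raw reads, counts per library and depths were not used here, so no spread between replicates, no outlying library and no detection limit could be computed.

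The tables were checked before use. The deposited log2 values lay within 0.001 of the ratio of the group values. The Col-0 values of both overexpression tables were identical for all 38303 genes, and the smallest q-value (0.00149) is shared by both tables and differs from an adjustment within either, so these q-values were adjusted over more tests than 1 table. In the BL table the q-values equal an adjustment over that table. The counts of the deposited subset tables at a q-value under 0.1 and at least 2-fold (518, 1478 and 186) were recounted and were identical when genes with a group at 0 FPKM were left out; the counts at this threshold given elsewhere include those genes. Group values of the hormone experiment and of the overexpression experiment come from separate Cuffdiff runs and are compared as levels, without a test of single genes. Of the loci 38085 were found by locus tag in the reference annotation, which gave symbols, classes and coordinates.

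Samples were grouped by the labels. The comparisons, gene lists, rule for named genes and the first set of alternatives were fixed before the data were examined. That design planned a model per library with limma, or with a count model for counts, a test of estimated correlation in the lists and fry; the deposited tables have no values per library, so the authors' tests were used for the calls and those models were not run. A gene was called at a deposited q-value under 0.05, without a filter on low values. A standard error was derived for each tested gene as the absolute log2 fold change over the absolute test statistic and over a constant k. The constant was the median, over genes with p-values between 0.0002 and 0.9, of the factor that turns the statistic into the normal deviate of the deposited p-value; k was 1.43 for BL, 1.42 for BEH2-YFP and 1.43 for BZR1-YFP. The median standard error was 0.204, 0.228 and 0.227. The BEH2-YFP effect minus the BZR1-YFP effect was tested by a two-sided normal test over the root of both squared standard errors, adjusted by Benjamini and Hochberg over 22336 genes.

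There were 40 gene lists, 30 written gene by gene and 10 by symbol prefix. All 440 written genes were matched, 433 by locus and symbol and 7 by locus alone, and 10 prefix hits of other families were left out. Lists with at least 4 tested members were tested by cameraPR of limma 3.58.1 in R 4.3.3 on the deposited test statistic, with a preset correlation of 0.01 between genes, and the 116 list tests were adjusted together. A correlation estimated from the libraries needs values per library, so which calls would hold with it is not known. Called members were counted over all genes tested and again adjusted over the list alone. Overlaps were tested by Fisher's exact test, two-sided, in 12 tests adjusted together, over genes tested in both tables. The chance values take these genes as independent and as equally likely to be called. The 4 set tests of the genes called with brassinolide were adjusted together. Named genes were the 6 BZR family members; per comparison up to 8 rises and 8 falls by size among called genes with a symbol and an FPKM of at least 5 in the higher group (the planned condition on replicates could not be applied); and in each list up to 4 called members by adjusted p, with CPD, DWF4, BR6OX2 and ROT3 in any case. The overlap and the difference of the lines followed the same rule by size. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

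The tests were tested on simulated data. With 100 genes shifted in 21011, the difference test called 34% of changes of 1 on the log2 scale and 85% of changes of 2, with 0 unchanged genes called. The normal test over the derived standard error, applied to BEH2-YFP against Col-0, called 68% and 94%, with 7 unchanged genes called. cameraPR called 4 of 100 random lists of 15 genes and 97 of 100 lists shifted by 1. These simulations took the derived standard errors as exact, the noise as normal and the genes as independent. Their low counts of false calls follow from that setting and do not give the error rate in the data. Shared-control simulations used 100 runs with a fixed seed. Alternatives were another threshold, a minimum FPKM of 1, quantile normalization, pseudocounts of 0.1 and 1, adjustment within each table, a normal test, protein-coding genes, genes with like Col-0 values in both experiments, a smaller variance for the difference, and ranks in the list test.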

Results

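Messenger RNA of whole Arabidopsis thaliana seedlings of the accession Col-0 was sequenced in 10 libraries, which fall into 5 groups of 2. Seedlings were 12 days old and had grown at 23 °C with 16 h of light and 8 h of dark. In the hormone experiment, Col-0 seedlings were treated for 6 h with mock or with 100 nM brassinolide (BL), the most active brassinosteroid. The labels differ on the control: the treatment protocol gives mock, while the sample titles and the treatment field call it non-treatment; it is named mock here. In the overexpression experiment, untreated Col-0 seedlings stood beside a line expressing BEH2-YFP and a line expressing BZR1-YFP, each from the constitutive 35S promoter. BZR1, BES1 and BEH1 to BEH4 form the family of transcription factors that act at the end of the brassinosteroid signalling pathway. The series asks whether BZR1 and BEH2 regulate different genes. The deposited tables give 1 pooled FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments) per gene and group for 38303 genes, so the depth of each library is unknown and no spread between replicates can be shown. Genes are called here at a q-value under 0.05 in the authors' deposited tables, and "rose" and "fell" are used of called genes. Folds are ratios of the authors' group values. The number after ± is the standard error of the log2 ratio implied by the deposited test statistic, which rests on 2 libraries per group. Coordinates are of the assembly TAIR10.1.

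Brassinolide against mock asks which genes respond to the hormone. Brassinosteroid synthesis genes fell, most tested genes with a SAUR symbol rose, and cell wall genes changed in both directions. DWF4, the rate-limiting synthesis enzyme (AT3G50660, chromosome 3, 18813949 to 18817405, minus strand), fell 11.4-fold, from 13.5 to 1.18 FPKM (log2 -3.52 ± 0.24). BR6OX2, which catalyses the last step of brassinolide synthesis, fell 47.4-fold, from 10.2 to 0.215 FPKM (log2 -5.57 ± 0.40). SAUR20, of a family of small auxin-induced proteins that promote cell expansion, rose 15.3-fold, from 0.759 to 11.6 FPKM (log2 3.93 ± 0.50). Untreated Col-0 of the other experiment stood at 14.0 FPKM for SAUR20. Of the transcription factor family itself, BEH2 (AT4G36780, chromosome 4, 17332269 to 17334355, minus strand) fell 7.75-fold, from 53.5 to 6.91 FPKM (log2 -2.95 ± 0.18). In the authors' deposited table, 1248 of 22864 tested genes (5.46%) were called, 688 higher and 560 lower, with a median fold of 1.79 among the higher and 1.81 among the lower; 482 of them changed at least 2-fold.

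Within the BZR family, BES1 (AT1G19350, chromosome 1, 6688463 to 6691216, plus strand) rose 1.83-fold with brassinolide, from 114 to 210 FPKM (log2 0.88 ± 0.18). BEH1 fell 1.89-fold, from 10.5 to 5.54 FPKM. BZR1 (AT1G75080, chromosome 1, 28185504 to 28188075, plus strand) stood at 23.0 FPKM in mock and 27.0 with brassinolide, which was not called (q = 0.763 in the authors' deposited table). BEH3 (8.54 and 8.83 FPKM) and BEH4 (14.0 and 15.4 FPKM) were not called either. As a list the 6 members had a median log2 change of 0.09 and a mean of -0.43, and the list test gave Down (adjusted p = 0.00197), so the median differs in sign from the mean and the test.

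Of 10 tested brassinosteroid synthesis genes 5 fell and 0 rose (7 and 0 adjusted over the list alone; list test adjusted p = 3.75e-29). Beside DWF4 and BR6OX2 these were CPD (AT5G05690, chromosome 5, 1702640 to 1706948, minus strand), from 126 to 25.2 FPKM, CYP90D1, from 5.80 to 0.979 FPKM, and ROT3, from 7.70 to 3.86 FPKM, all cytochrome P450 enzymes of the pathway. Of 7 inactivation genes 2 rose and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.00054): BAS1, a hydroxylase that inactivates brassinosteroids, rose 3.59-fold (log2 1.84 ± 0.18) and BEN1 rose 1.78-fold (log2 0.83 ± 0.20). Of 9 signalling genes 3 fell, all of them receptors (adjusted over the list alone 3 fell and 2 rose): the receptor BRI1 fell from 42.9 to 23.8 FPKM, and its homologues BRL1 and BRL3 fell 1.66-fold and 2.19-fold. That list was not called as a set (adjusted p = 0.0822).

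Of 15 tested SAUR genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 1.12e-32). SAUR22 rose 10.3-fold, SAUR24 from 0.887 to 8.87 FPKM, SAUR9 8.27-fold and SAUR63 6.03-fold. SAUR20, SAUR22 and SAUR24 belong to a cluster of near-identical genes, for which the sharing of reads was not analysed here. Only genes whose symbol starts with SAUR are in the list. AT5G18030, described as SAUR-like, lies outside it and rose 10.8-fold. Untreated Col-0 of the other experiment stood at 9.50 FPKM for SAUR24, above its brassinolide value. For SAUR9 (1.85 FPKM) and SAUR63 (7.94 FPKM) it stood below theirs (8.45 and 13.3 FPKM). Of 27 xyloglucan endotransglucosylase/hydrolases, enzymes that remodel the wall, 8 rose and 5 fell (10 and 7 adjusted over the list alone; adjusted p = 9.08e-05). XTH19 rose 7.08-fold, from 4.65 to 32.9 FPKM, XTH17 rose 5.75-fold, and XTH4 rose from 346 to 918 FPKM. Of 23 expansins 6 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.0232); EXPA8 rose 3.77-fold and EXPA18, an expansin of root hairs, fell 2.70-fold. Of 16 genes of cellulose synthesis and secondary walls 3 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.00597): CESA1, a cellulose synthase subunit, rose from 97.4 to 142 FPKM, COB from 84.2 to 131 FPKM and CSI1 from 30.4 to 41.8 FPKM. TCH4, a touch-induced wall enzyme, rose 2.61-fold. Of 12 root hair genes 7 fell and 1 rose (9 and 2 adjusted over the list alone; adjusted p = 1.49e-06), among them the wall protein genes PRP3, 2.60-fold lower, and PRP1, 2.18-fold lower, while LRX2 rose 3.07-fold. EXT10, an extensin, fell 6.39-fold, and TPD1, known from anther development, fell 8.16-fold.

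Among regulators, KDR, an atypical bHLH protein, rose 9.10-fold, from 3.19 to 29.0 FPKM (log2 3.19 ± 0.23), and BEE3, a bHLH factor of the early brassinosteroid response, rose 1.70-fold. BS1 (AT1G74500, also named PRE3) fell 4.47-fold and IBH1, a growth repressor, fell 1.74-fold. In this bHLH list of 15, 2 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 7.13e-05, up). Of 23 light signalling regulators 5 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.00394); PIF7 fell 2.67-fold, GPRI1, a factor of chloroplast development, 2.06-fold, GATA2 1.90-fold and PIF3 1.72-fold. Of 13 cytokinin response genes 2 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 7.98e-05), with ARR7, a type-A response regulator, 3.76-fold lower and ARR4 1.42-fold lower. ESE3, a factor of the ERF family, rose 7.19-fold. The auxin response gene IAA19 rose 2.95-fold, and the auxin importer LAX3 fell 3.15-fold.

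In metabolism and defence, 4 of 11 genes of the list named indole glucosinolate and camalexin fell and 1 rose (4 and 1 adjusted over the list alone, list test adjusted p = 0.0149). The camalexin synthesis genes CYP71A13 and PAD3 are not in that list. CYP83B1 fell from 339 to 225 FPKM and the methyltransferase gene IGMT1 rose from 42.5 to 77.4 FPKM. Of 17 nitrate and phosphate genes 4 rose and 4 fell (6 and 5 adjusted over the list alone): the nitrate reductase gene NIA1 fell 2.29-fold, NIR1 fell 1.74-fold, and ASN1, an asparagine synthetase, rose 3.02-fold. That list was not called as a set (adjusted p = 0.502). Of 17 ethylene genes 4 fell and 0 rose (4 and 2 adjusted over the list alone), among them ACS7, an ethylene synthesis enzyme, 5.77-fold lower; ACS11 went from 0.953 FPKM to a value listed as 0. The ethylene list was not called (adjusted p = 0.296), and its mean (0.50) differs in sign from its median (-0.05) and its test. Of 23 salicylate and pathogen defence genes 4 rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.0488), with the defence marker PR1 2.00-fold higher. LOX2, an enzyme of jasmonate synthesis, fell 5.65-fold, from 51.6 to 9.14 FPKM. DIN11, a gene induced in the dark, fell 5.85-fold. The heat shock list (11 tested) and the ribosomal protein list (55 tested) had 0 members called by Cuffdiff in the authors' deposited table, with 2 and 1 members at an unadjusted p under 0.05.

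By the set test of limma's cameraPR 15 of 38 lists were called with brassinolide, 7 up and 8 down. With ranks in place of the statistic the calls ended for the BZR family (adjusted p = 0.836), inactivation (0.129), light signalling (0.296), salicylate (0.093), flavonoid (0.137), expansin (0.297) and xyloglucan enzyme (0.349) lists. Counting genes at a q-value under 0.1 with at least a 2-fold change gave 526 genes.

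**Figure D1:**
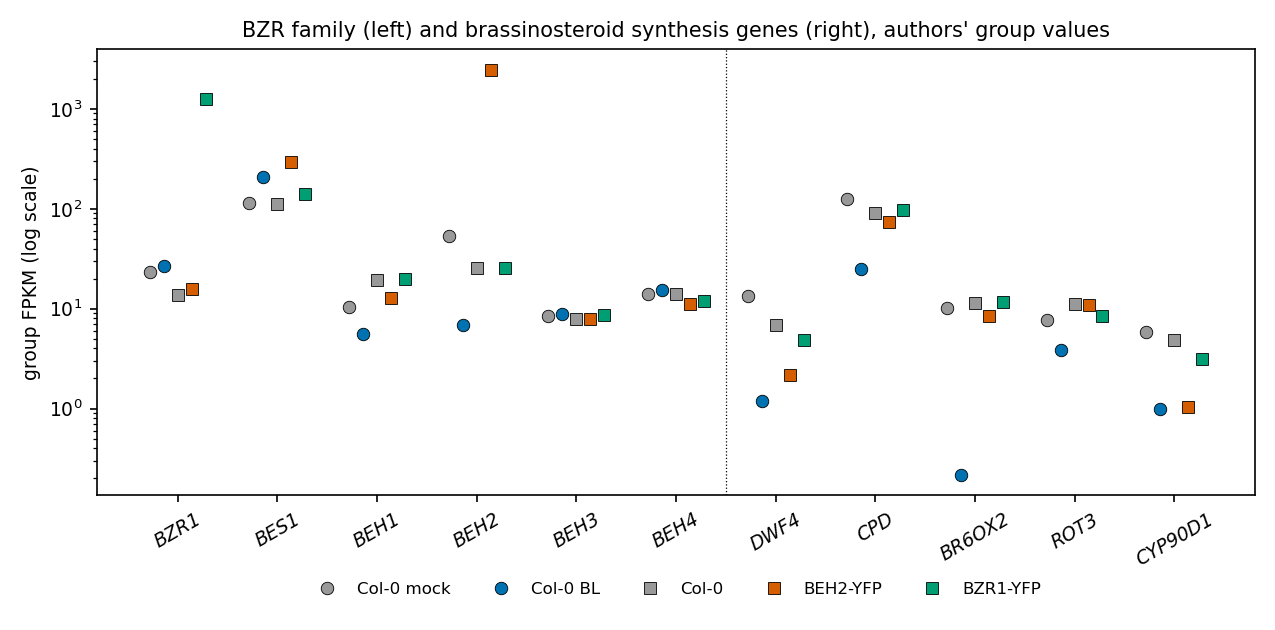
Group FPKM (log scale) of the 6 BZR family genes and of 5 brassinosteroid synthesis genes; circles are the hormone experiment and squares the overexpression experiment, 1 authors' value per group of 2 libraries. BEH2 stood at 2477 FPKM in BEH2-YFP and BZR1 at 1265 FPKM in BZR1-YFP, and the 5 synthesis genes were lower with brassinolide than in mock.

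BEH2-YFP against Col-0 asks what an excess of BEH2 changes. The BEH2 transcript rose 96.0-fold, from 25.8 to 2477 FPKM (log2 6.59 ± 0.30), and with it changed members of the senescence, jasmonate, salicylate, cell wall and flowering lists. The defence marker PR1 (chromosome 2, 6241640 to 6242541, minus strand) rose 32.9-fold, from 15.2 to 500.1 FPKM (log2 5.04 ± 0.21). BAM5, a beta-amylase (chromosome 4, 8666334 to 8669526, minus strand), rose 70.5-fold, from 12.9 to 909 FPKM (log2 6.14 ± 0.24). PDF1.2, a defensin of the ethylene and jasmonate response (chromosome 5, 17906968 to 17907638, minus strand), fell 171-fold, from 293 to 1.72 FPKM (log2 -7.42 ± 0.39), while Col-0 mock of the other experiment stood at 3.74 FPKM. In the authors' deposited table, 2691 of 22729 tested genes (11.8%) were called, 1662 higher and 1029 lower, with median folds of 2.11 and 1.90; 1378 changed at least 2-fold.

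Of the family, BES1 rose 2.63-fold in BEH2-YFP, from 112 to 296 FPKM (standard error 0.21 on the log2 scale), and BEH1 fell 1.49-fold, from 19.2 to 12.8 FPKM. BZR1 (13.8 and 15.7 FPKM), BEH3 (7.86 and 7.94 FPKM) and BEH4 (14.1 and 11.1 FPKM) were not called. Of 10 synthesis genes 3 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.00394). CYP90D1 fell 4.76-fold, DWF4 3.19-fold, from 6.91 to 2.17 FPKM, and BR6OX1 2.89-fold. CPD (90.0 and 74.3 FPKM), BR6OX2 (11.5 and 8.37 FPKM) and ROT3 (11.2 and 10.8 FPKM) were not called. Of 7 inactivation genes 1 rose, BAS1 (2.58-fold), and 1 fell, BAT1 (1.47-fold, from 30.7 to 20.8 FPKM), with 2 and 1 adjusted over the list alone; the list was not called (adjusted p = 0.658). Of the bHLH list 4 of 15 rose and 3 fell (4 and 6 adjusted over the list alone), with BEE3 higher (from 11.5 to 34.5 FPKM), BEE1 2.69-fold higher and HFR1, a light signalling factor, 4.03-fold lower; the list was not called as a set (adjusted p = 0.757).

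Of 12 senescence genes 9 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 2.96e-15). SAG13 rose 11.0-fold, from 16.3 to 180 FPKM (log2 3.46 ± 0.20), the sugar transporter gene SAG29 8.31-fold, NAC6, a regulator of leaf senescence, 3.42-fold, and SAG21 3.27-fold. Of 23 jasmonate genes 12 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 6.35e-05). JAZ10, a repressor induced by jasmonate, rose 7.03-fold, LOX2 5.22-fold, from 189 to 988 FPKM, and the synthesis enzyme AOC1 4.18-fold. Of 59 WRKY transcription factor genes 19 rose and 5 fell (23 and 9 adjusted over the list alone; adjusted p = 1.54e-05); WRKY48 rose 7.59-fold, WRKY18 6.21-fold and WRKY60 4.52-fold. Of 23 salicylate and pathogen defence genes 5 rose and 7 fell (6 and 10 adjusted over the list alone). SARD1, a regulator of salicylate synthesis, rose 3.71-fold and WRKY70 fell 2.92-fold; the list was not called (adjusted p = 0.721), and its median (-0.30) differs in sign from its mean (0.08) and test. Of 17 ethylene genes 5 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.081), with ERF2 1.99-fold higher and ACS6 2.81-fold lower.

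Among called genes with a symbol and at least 5 FPKM in the higher group, the largest falls beside that of PDF1.2 were those of PCR1, of a family linked to cadmium resistance (62.2-fold, from 12.7 to 0.205 FPKM), PDF1.3 (37.4-fold), DIN11 (17.1-fold), SIB1 (16.8-fold), PCC1 (16.2-fold), the thionin gene THI2.1 (8.30-fold) and the nitrilase gene NIT4 (6.63-fold). Among the largest rises by the same rule were the nitrate transporter gene NRT1.8 (68.2-fold, from 0.680 to 46.4 FPKM), DXPS1 (47.3-fold), the transporter gene UMAMIT25 (42.0-fold), EARLI1 (38.6-fold, from 50.5 to 1945 FPKM), CYP82C2 (37.8-fold) and XTH11 (36.1-fold). PDF1.2 and PDF1.3 are near-identical in sequence, and how their reads were shared was not analysed here.

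Of 27 xyloglucan enzymes 13 rose and 2 fell in BEH2-YFP (14 and 4 adjusted over the list alone; adjusted p = 1.14e-08); XTH25 rose 11.0-fold, XTH4 4.21-fold, from 110 to 462 FPKM, and XTH7 3.93-fold. Of 15 SAUR genes 10 rose and 0 fell (10 and 1 adjusted over the list alone; adjusted p = 3.5e-05), with SAUR9 8.57-fold and SAUR15 3.04-fold higher. Of 21 expansins 6 fell and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 0.00127); EXPA11 fell 3.04-fold and EXPA8 2.93-fold, while EXLA1 rose 10.5-fold. Of 12 root hair genes 7 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 9.08e-05), PRP1 2.45-fold and PRP3 2.02-fold lower. Of 12 touch and wounding genes 5 fell and 1 rose (6 and 2 adjusted over the list alone; adjusted p = 9.08e-05), among them the zinc finger gene STZ (4.08-fold) and ERF6 (3.78-fold), with WRKY6 3.34-fold higher.

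Of 13 flower and flowering time genes 4 fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 1.31e-05): the floral identity genes AP1 (from 3.61 to 0.120 FPKM) and PI (3.73-fold), AGL8 (4.67-fold) and the flowering activator AGL20 (1.94-fold). Of 19 gibberellin genes 4 rose and 0 fell (8 and 1 adjusted over the list alone; adjusted p = 0.00938), among them the synthesis enzymes GA3 (2.48-fold) and GA3OX1 (2.31-fold) and the receptor GID1B (2.39-fold). Of 16 genes of auxin transport and synthesis 5 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0188), LAX3 1.96-fold and PIN7 1.62-fold lower. Of 13 cytokinin response genes 3 fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p = 0.00903), with the type-A regulator ARR15 2.87-fold lower. Of 17 flavonoid genes 5 rose and 3 fell (6 and 5 adjusted over the list alone; adjusted p = 0.132); DFR, LDOX and PAP1, which act in anthocyanin synthesis, rose 6.95-fold, 5.64-fold and 4.19-fold, and FLS1, of flavonol synthesis, fell 2.43-fold. Of 14 aliphatic glucosinolate genes 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0391), with MYB76 3.33-fold and CYP79F1 1.83-fold lower. GH3.3, an enzyme that conjugates auxin, rose 17.3-fold, from 4.24 to 73.6 FPKM; the GH3 list of 4 was called up (adjusted p = 0.00106) with a mean of 0.83 and a median of -0.02, which differ in sign. The 53 light-harvesting and photosystem genes had a median log2 change of -0.31 with 1 called higher and 2 lower (adjusted p = 0.0165). Of these, 8 are encoded in the chloroplast (median -2.06) and 45 in the nucleus (median -0.28). Over all tested chloroplast-encoded genes the median was -1.01, over snRNA genes -0.75 and over snoRNA genes -0.39, and the 1 rRNA locus tested fell (log2 -1.60). With brassinolide these medians were 0.032, -0.0061 and -0.13, and the rRNA locus had a log2 change of 0.39. The cause of the lower values in the line was not tested.

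By cameraPR 20 of 39 lists were called in BEH2-YFP, 9 up and 11 down, among them the BZR family list, which holds the transgene itself; with ranks the calls ended for the BZR family (adjusted p = 0.675), GH3 (0.855) and class III peroxidase (0.152) lists. At a q-value under 0.1 with at least a 2-fold change, genes with a group at 0 FPKM included, 1514 genes were counted, and among genes whose Col-0 value lay within 2-fold of Col-0 mock of the other experiment 1628 were called. Of the genes called in BEH2-YFP and not in BZR1-YFP that have values in all groups (2398), 721 had a Col-0 mock value more than 2-fold from Col-0 on the side to which the line moved and 148 on the other side. Col-0 enters both the call and this comparison, which by itself favours the line's side.

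BZR1-YFP against Col-0 asks the same of BZR1. The BZR1 transcript rose 91.9-fold, from 13.8 to 1265 FPKM (log2 6.52 ± 0.26), and fewer other genes were called than in BEH2-YFP. GH3.3 rose 3.80-fold, from 4.24 to 16.1 FPKM (log2 1.92 ± 0.21), and SAG29 rose 5.43-fold, from 1.82 to 9.90 FPKM (log2 2.44 ± 0.30). PDF1.2 fell 5.58-fold, from 293 to 52.6 FPKM (log2 -2.48 ± 0.20). In the authors' deposited table, 367 of 22605 tested genes (1.62%) were called, 259 higher and 108 lower, with median folds of 1.85 and 1.93; 159 changed at least 2-fold.

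No other family member was called in BZR1-YFP: BES1 stood at 112 and 140 FPKM, BEH1 at 19.2 and 20.0, BEH2 at 25.8 and 25.7, BEH3 at 7.86 and 8.59, and BEH4 at 14.1 and 12.0 FPKM. Of the 10 synthesis genes 0 were called by Cuffdiff in the authors' deposited table, and 3 were lower at an unadjusted p under 0.05. DWF4 stood at 6.91 and 4.82 FPKM (log2 -0.52 ± 0.22), CPD at 90.0 and 96.1, BR6OX2 at 11.5 and 11.7, and ROT3 at 11.2 and 8.37 FPKM. BEE3 rose 1.75-fold.

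Of 11 senescence genes 6 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 1.06e-14), with SAG13 2.17-fold, NAC6 1.97-fold and the senescence regulator NAP 1.61-fold higher. Of 15 SAUR genes 5 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 1.18e-10), among them SAUR15 (2.33-fold), SAUR63 (2.06-fold) and SAUR24 (2.00-fold). Of 23 salicylate and pathogen defence genes 4 rose and 0 fell (10 and 1 adjusted over the list alone; adjusted p = 6.06e-07): FRK1, a marker of the response to bacterial flagellin, rose 5.32-fold, the camalexin synthesis genes CYP71A13 and PAD3 rose 5.18-fold and 2.88-fold, and WRKY18 rose 2.05-fold. Of 27 xyloglucan enzymes 4 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0068), with XTH25 2.79-fold and XTH7 1.96-fold higher. Of 23 abscisic acid and drought genes 2 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00163), RD20 2.05-fold and LTI65 4.07-fold. Other large rises were those of SADHU3-2, a retroposon (19.2-fold), MT1B, of the metallothioneins (4.34-fold), LTP4, a lipid transfer protein (3.95-fold), and AZI1, of systemic immunity (3.12-fold).

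Of 12 touch and wounding genes 5 fell and 0 rose (6 and 1 adjusted over the list alone; adjusted p = 0.000194): ORA47 fell 1.85-fold, ERF104 1.81-fold, STZ 1.77-fold and ERF6 1.70-fold. Of 16 nitrate and phosphate genes 3 fell and 0 rose, also adjusted over the list alone; IPS1, a noncoding RNA of phosphate starvation, fell 5.66-fold, PS2 2.23-fold and the glutamine synthetase gene GLN1 (AT5G16570) 2.02-fold. That list was not called (adjusted p = 0.247), and its median (0.17) differs in sign from its mean (-0.08) and test. PAP14, of the purple acid phosphatases, fell 10.8-fold, from 6.96 to 0.643 FPKM. Col-0 mock of the other experiment stood at 0.061 FPKM for PAP14, and at 3.60 FPKM for PS2 beside 26.7 in Col-0. The defensin genes PDF1.3, PDF1.2b and PDF1.2c fell 14.3-fold, 9.52-fold and 7.44-fold. For PDF1.2c, Col-0 mock of the other experiment stood at 0.896 FPKM, beside 155 in Col-0 and 20.8 in BZR1-YFP. How reads were shared among these defensin genes was not analysed here. Of 21 expansins 2 fell and 0 rose, also adjusted over the list alone, EXPB1 1.58-fold and EXPA8 1.54-fold; the list was not called (adjusted p = 0.272). Of 12 root hair genes 0 were called by Cuffdiff in the authors' deposited table, also adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Their median log2 change was -0.41 and the list test gave Down (adjusted p = 0.0053). Of 23 jasmonate genes 2 rose and 2 fell (adjusted p = 0.443), with AOC1 1.97-fold higher and the methyltransferase gene JMT 2.60-fold lower.

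By cameraPR 14 of 39 lists were called in BZR1-YFP, 11 up and 3 down, among them the BZR family list, whose rise was that of the transgene; with ranks the calls ended for the BZR family (adjusted p = 0.352) and the GH3 list (0.92), whose median (-0.06) differs in sign from its mean (0.40). The count of called genes was 195 when the p-values were adjusted within this table alone (3118 for BEH2-YFP within its own), 197 at a q-value under 0.1 with at least a 2-fold change (genes with a group at 0 FPKM included), and 148 among genes whose Col-0 value lay within 2-fold of Col-0 mock. With adjustment within the table, of the 53 called genes picked by the rule for named genes 37 kept their call; the calls that ended include those of FRK1, SAUR63, LTI65, ORA47, EXPB1, EXPA8, JMT and, outside that rule, GSTU4. Called members then numbered 4 of the senescence list, 2 of the SAUR list, 3 of the salicylate list and 1 of the abscisic acid list, all higher, 3 of the touch list, all lower, and 1 higher and 1 lower of the jasmonate list.

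**Figure D2:**
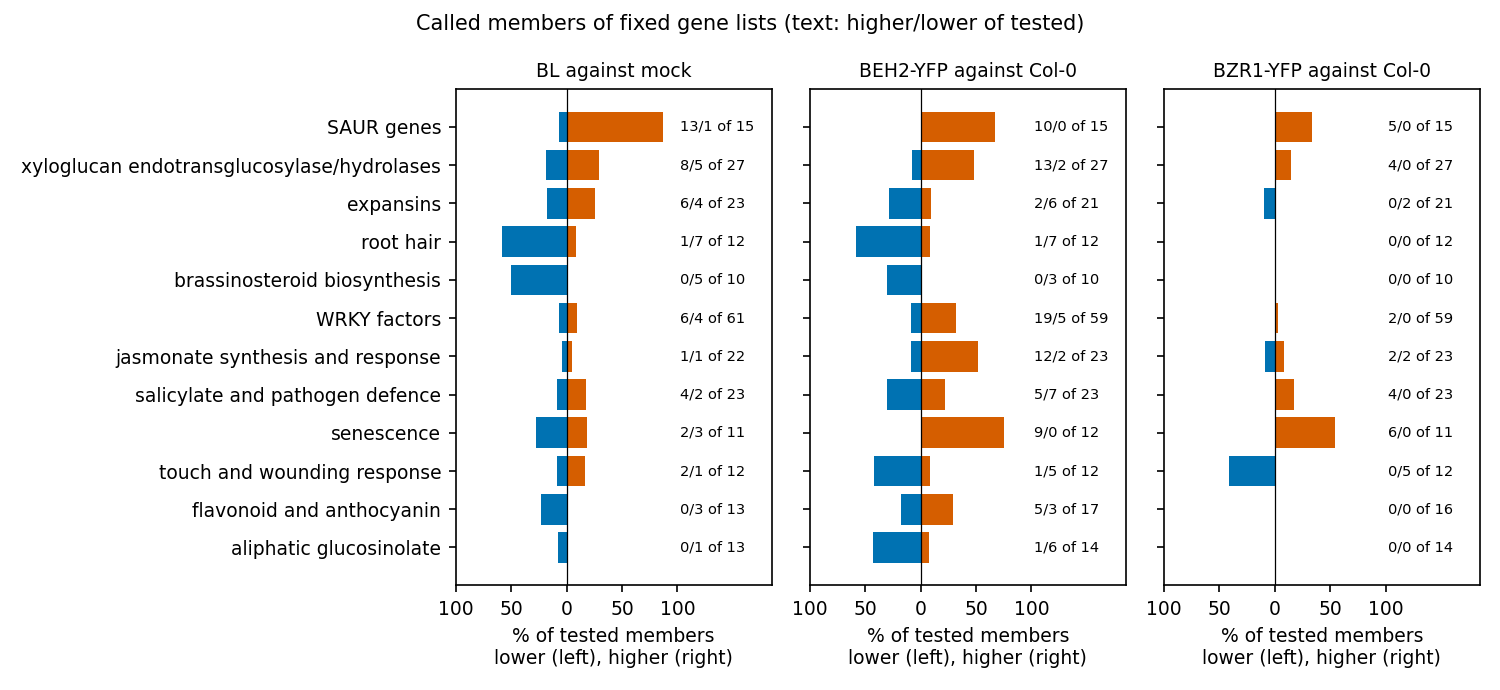
Percent of the tested members of 12 gene lists called higher (right) or lower (left) in each comparison, with the counts beside the bars. Of 15 SAUR genes 13, 10 and 5 were called higher with brassinolide, in BEH2-YFP and in BZR1-YFP, and of 12 root hair genes 7, 7 and 0 were called lower.

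The lines were then compared with each other, as the BEH2-YFP effect minus the BZR1-YFP effect. Among genes called in this test with a symbol and at least 5 FPKM in the highest of the groups, PCR1, PDF1.2c and BAM5 differed most beside both transgenes. BAM5 stood at 909 FPKM in BEH2-YFP and 22.4 in BZR1-YFP, a difference of 5.34 ± 0.30 on the log2 scale. PR1 stood at 500.1 and 23.0 FPKM (difference 4.44 ± 0.30), and EXT4, an extensin, at 2350 and 129 FPKM (difference 4.18 ± 0.35). PCR1 stood at 0.205 FPKM in BEH2-YFP, 31.8 in BZR1-YFP and 12.7 in Col-0 (difference -7.28 ± 0.73). In the authors' Cuffdiff test of BEH2-YFP against Col-0 its p-value was 0.0007, with log2 -5.96 and a derived standard error of 0.69. A normal test over that error would give a far smaller p-value. The derived error is therefore too small for PCR1, and so is that of its difference. Of 22336 genes compared, the effects of 802 differed at an adjusted p under 0.05, with 515 higher in BEH2-YFP and the others lower; 748 of them were called in BEH2-YFP and 130 in BZR1-YFP.

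XTH11 (31.7 and 1.35 FPKM), NRT1.8 (46.4 and 2.70 FPKM), EARLI1 (1945 and 121 FPKM) and UF3GT, an enzyme of anthocyanin glycosylation (7.35 and 0.416 FPKM), were also higher in BEH2-YFP than in BZR1-YFP by this test. PDF1.2c (0.177 and 20.8 FPKM), PDF1.2 (1.72 and 52.6 FPKM), PCC1 (2.50 and 36.7 FPKM), SIB1 (0.799 and 9.36 FPKM), DIN11 (0.584 and 5.11 FPKM) and SADHU3-2 (0.711 and 10.7 FPKM) were lower. PDF1.2c was not called in BEH2-YFP against Col-0 by the authors' test, although its log2 change was -9.77. Its derived standard error (1.13) is therefore too small as well, and its call in the test of the difference is not reliable. The standard error of a difference was taken from both contrasts as if each had its own Col-0, which makes it too large; with a part of each variance (0.5 of it) left out as the shared control's, 2281 genes differed.

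The overlap of the lines asks how far BZR1-YFP and BEH2-YFP changed the same genes. The lines called 264 genes in the same direction. Genes called higher in both lines were 10.2 times as many as the 18.3 of chance (Fisher's exact test, two-sided, adjusted p = 2.33e-156), and 78 were called lower in both against 4.95 (adjusted p = 1.11e-79). These were 73.8% of the higher and 72.2% of the lower calls of BZR1-YFP. PDF1.2, PDF1.3 and STZ fell in both lines, and GH3.3, SAG13, SAG29, XTH7, XTH25, WRKY18 and BEE3 rose in both. The lines moved 4 genes in opposite directions: PCR1, ABCG40, GSTU4 and AT3G05727, the last of which rose from 37.8 to 137 FPKM in BEH2-YFP and fell to 21.3 FPKM in BZR1-YFP (ABCG40, GSTU4 and AT3G05727 were named after their values were seen).

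Both contrasts use the same Col-0 libraries, which alone makes their fold changes correlate. Over 21011 genes with a standard error under 1, the correlation across genes was 0.553, against 0.499 simulated for unchanged lines with a shared control, and the covariance was 0.119 against 0.0505; genes are not independent replicates. The simulation gave a mean of 4.31 genes called in the same direction, and at most 9 in 100 runs, against 264. It took both lines as unchanged and let Col-0 vary only within the derived standard errors. In the data the median absolute fold change over its standard error was 1.42 (BEH2-YFP) and 0.77 (BZR1-YFP) times the normal value, so the setting matches neither line. It therefore cannot tell changes shared by the lines from a Col-0 group that stood further apart. Of the shared calls with values in all groups (262), 135 had a Col-0 mock value more than 2-fold from Col-0 on the side to which the lines moved, 30 on the other side, and 97 lay within 2-fold; for genes called in BZR1-YFP and not in BEH2-YFP 23 lay on the line's side and 19 on the other. AZI1, for example, stood at 995 FPKM in Col-0 mock and 33.9 in Col-0, and PDF1.2 at 3.74 and 293 FPKM. The same Col-0 values set the called direction, so this comparison by itself favours the lines' side. Of the overlap 97 genes remained when genes with Col-0 beyond 2-fold of Col-0 mock were left out, 144 when p-values were adjusted within each table, and 114 at a q-value under 0.1 with at least a 2-fold change.

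The genes called with brassinolide were followed into both lines, which asks whether excess transcription factor moves the hormone's genes. Of the genes that rose with brassinolide 214 also rose in BEH2-YFP, against 49.5 by chance (Fisher's exact test, two-sided, adjusted p = 2.58e-80), and of those that fell 144 also fell, against 24.6 (adjusted p = 3.34e-70). SAUR9 rose 8.27-fold with brassinolide and 8.57-fold in BEH2-YFP, SAUR15 17.2-fold and 3.04-fold, and PRX52, a peroxidase, 3.11-fold and 5.08-fold. Their controls differed: Col-0 mock and Col-0 stood at 1.02 and 1.85 FPKM for SAUR9, 0.273 and 5.26 for SAUR15, and 2.12 and 6.47 for PRX52. For SAUR15 Col-0 lay above the brassinolide value (4.70 FPKM). CYP90D1 fell 5.93-fold and 4.76-fold, DWF4 11.4-fold and 3.19-fold, and DIN11 5.85-fold and 17.1-fold. Genes also moved in opposite directions more often than by chance: 103 that fell with brassinolide rose in BEH2-YFP against 39.9 (adjusted p = 6.93e-19), and 45 that rose with it fell against 30.5 (adjusted p = 0.0116). Chance here takes all tested genes as independent and equally likely to be called. Genes that are called more easily in both experiments would raise overlaps in either direction, which was not tested. The excess alone therefore does not show shared regulation. LOX2 fell 5.65-fold with brassinolide, from 51.6 to 9.14 FPKM, and rose 5.22-fold in BEH2-YFP, from 189 to 988 FPKM. EXPA8 rose 3.77-fold and fell 2.93-fold, but from unlike controls, 12.6 FPKM in Col-0 mock and 131 in Col-0. It reached like levels, 47.3 FPKM with brassinolide and 44.6 in BEH2-YFP.

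In BZR1-YFP 41 genes that rose with brassinolide also rose, against 7.63 by chance (Fisher's exact test, adjusted p = 2.1e-18), and 21 that fell also fell, against 2.39 (adjusted p = 3.26e-14). In the opposite direction 32 that fell rose, against 6.14 (adjusted p = 3.31e-14), and 7 that rose fell, against 2.96 (adjusted p = 0.0291). The ratios to chance were 5.38 and 8.80 in the same direction and 5.21 and 2.36 in the opposite direction. The limit given above on the chance values holds here too. AZI1 fell with brassinolide, from 995 to 462 FPKM, and rose in BZR1-YFP, from 33.9 to 106 FPKM. Over all genes that rose with brassinolide, the median log2 change was 0.23 in BEH2-YFP, with 64.2% positive, and 0.11 in BZR1-YFP, with 67.6% positive; the cameraPR set test of limma gave adjusted p = 1.34e-09 and adjusted p = 0.000109 (4 such tests adjusted together). Over those that fell it was -0.24 (37.3% positive, adjusted p = 0.139) and -0.06 (43.9% positive, adjusted p = 0.188), which were not called; with ranks in place of the statistic both were called down (adjusted p = 0.00147 and 0.0243). Same-direction genes numbered 358 in BEH2-YFP and 62 in BZR1-YFP; at a q-value under 0.1 with at least a 2-fold change they numbered 133 and 18, and 29 in BZR1-YFP with adjustment within the table.

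**Figure D3:**
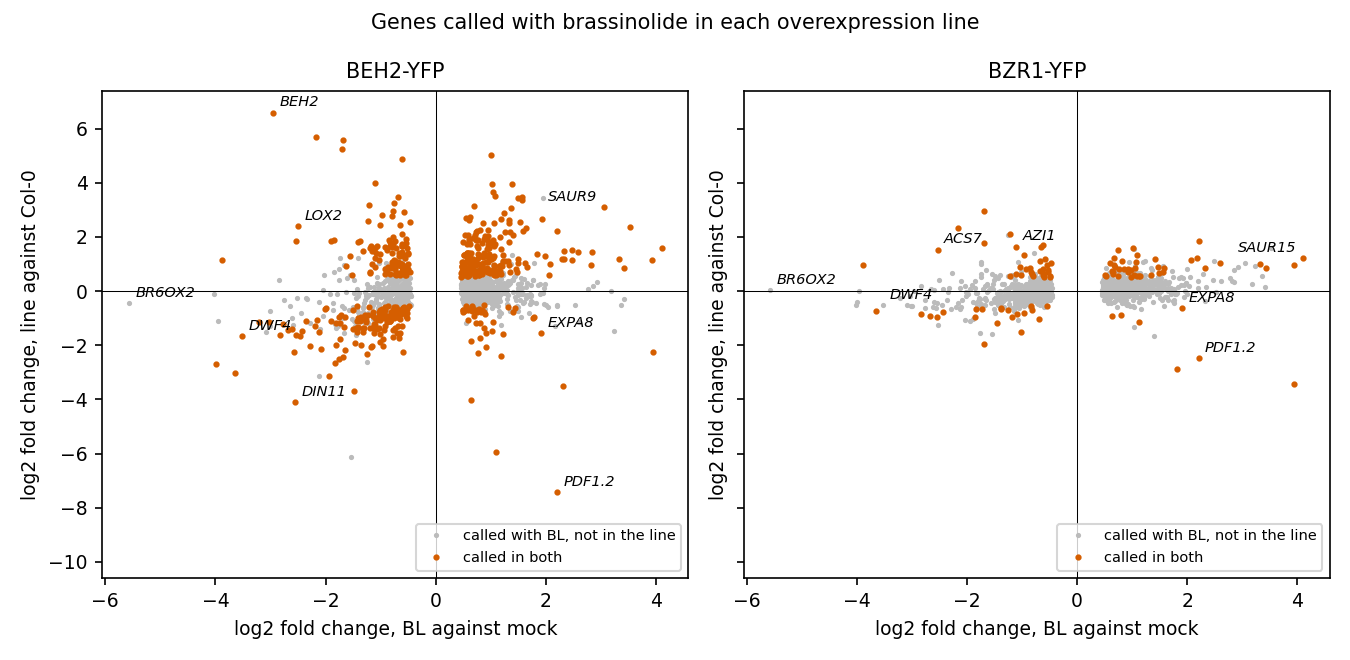
Log2 fold change with brassinolide (horizontal axis) and in each line (vertical axis) of the genes called with brassinolide, leaving out those with a group listed at 0; orange points were also called in the line. Points lie in all quadrants, with 358 same-direction and 148 opposite calls in BEH2-YFP and 62 and 39 in BZR1-YFP.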

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

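The tests of the Col-0 groups, of the brassinolide direction, of precision, of transgene level and of the overlapping gene were chosen after the results were seen; the test of shared sequence between BEH2 and BES1 was chosen before its result was seen. The effects of the lines differed by the test of the difference itself for the genes below, given as the BEH2-YFP effect minus the BZR1-YFP effect on the log2 scale. The transgenes themselves differed by 6.59 (BEH2) and -6.33 (BZR1). Higher in BEH2-YFP were BAM5 by 5.34, XTH11 by 4.55, PR1 by 4.44, EXT4 by 4.18, UF3GT by 4.14, NRT1.8 by 4.10 and EARLI1 by 4.01. Lower in BEH2-YFP were PCR1 at -7.28, PDF1.2c at -6.88, PDF1.2 at -4.94, SADHU3-2 at -3.91, PCC1 at -3.88, SIB1 at -3.55 and DIN11 at -3.13. PCR1 and PDF1.2c stood at 0.205 and 0.177 FPKM in BEH2-YFP. For both, the derived standard error is too small beside the authors' test, which did not call PDF1.2c in BEH2-YFP. Of the genes called in opposite directions, PCR1 is given above, ABCG40 differed by -1.97, GSTU4 by -1.93 and AT3G05727 by 2.68.

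The first pattern is the set of 264 genes called in the same direction in both lines. A candidate explanation is a Col-0 group that stood apart from other Col-0 seedlings. Col-0 mock lay more than 2-fold from Col-0 on the lines' side for 135 of these genes and on the other side for 30 (exact binomial test, which takes genes as independent, p = 4.16e-17). The same Col-0 values set both the called direction and the side. Genes picked for a Col-0 value far from the lines favour the lines' side in advance. The test against an even split therefore cannot decide whether Col-0 stood apart. Genes called in neither line have no called direction to compare with. Among 19615 of them Col-0 mock lay more than 2-fold above Col-0 for 1169 and more than 2-fold below it for 1429. The skew is not particular to the shared genes, since it also holds for those called in BEH2-YFP and not in BZR1-YFP (721 and 148), while those called in BZR1-YFP and not in BEH2-YFP gave 23 and 19. A brassinosteroid response may contribute too, since of the shared genes also called with brassinolide 53 moved with it as in the lines and 31 the other way (exact binomial test p = 0.0214). Both stay open and do not exclude each other; the groups also come from separate Cuffdiff runs, and the labels differ on whether the hormone control was mock-treated or untreated, so what sets its levels apart from Col-0 is not known.

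The second pattern is the larger number of calls in BEH2-YFP. Lower precision of the BZR1-YFP contrast is argued against: given the BZR1-YFP standard errors, the BEH2-YFP fold changes gave 3444 calls in the normal test (3257 with their own), against 242 for BZR1-YFP in the same test. Among genes with Col-0 within 2-fold of Col-0 mock the calls were 1628 in BEH2-YFP and 148 in BZR1-YFP. The transgene transcript in BEH2-YFP stood at 1.96 times the level of that in BZR1-YFP, and with 1 line per gene the transcript level and the identity of the protein cannot be told apart. A difference between the proteins therefore stays open as untested.

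The third pattern is genes that rose with a transgene and may carry its reads. For BES1, which rose in BEH2-YFP, 0.0399% of the 25-base words of its transcripts (1 of 2507) occur in BEH2 transcripts, while the rise in BES1 FPKM was 7.48% of the rise in BEH2, so reads shared with the transgene are argued against. AT1G09523, a noncoding gene on the minus strand within BZR1 (chromosome 1, 28186684 to 28186903, named after its values were seen), rose from 25.5 to 2388 FPKM in BZR1-YFP. Its ratio to BZR1 was 2.11, 1.84, 1.86, 1.63 and 1.89 in Col-0 mock, Col-0 BL, Col-0, BEH2-YFP and BZR1-YFP, a range of 1.29 times, which is consistent with BZR1 reads counted for both genes.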

How the results depend on the processing

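All alternatives below except the threshold, the minimum FPKM, quantile normalization and the pseudocounts were chosen after seeing the data. At a q-value under 0.1 with at least a 2-fold change, genes with a group at 0 FPKM included, the calls were 526 (BL), 1514 (BEH2-YFP) and 197 (BZR1-YFP), the overlap of the lines 114, and the brassinolide genes moved in the same direction 133 in BEH2-YFP and 18 in BZR1-YFP, since that threshold leaves out smaller changes. Adjustment within each table gave 195 calls in BZR1-YFP but 3118 in BEH2-YFP, an overlap of 144 and 29 brassinolide genes in BZR1-YFP. The deposited q-values of both tables were not adjusted within either. Both tables share the same cut, a largest called p-value of 0.00335 in the authors' Cuffdiff tests. With adjustment within the tables the largest called p-value was 0.00685 in BEH2-YFP and 0.0004 in BZR1-YFP. The shared cut is thus stricter for BEH2-YFP and looser for BZR1-YFP, which gives the opposite moves by construction. Genes with Col-0 within 2-fold of Col-0 mock held 1628 BEH2-YFP calls, 148 BZR1-YFP calls and 97 shared calls; the cause was not tested. The effects of the lines differed for 2281 genes with 0.5 of each variance left out, by construction of a smaller error. With ranks the BZR family list with BL turned to up (adjusted p = 0.836) and the GH3 list in BZR1-YFP to down (adjusted p = 0.92), and the genes lowered by brassinolide, as a set, passed as down in BEH2-YFP (adjusted p = 0.00147) and BZR1-YFP (adjusted p = 0.0243); the cause was not tested. The counts stayed within 1.5 times under a minimum FPKM of 1, under quantile normalization, which moved the median of all genes by -0.0034, -0.037 and -0.015, in the normal test and among protein-coding genes. Of 116 list tests, 108 kept their direction and side of the threshold under quantile normalization, 1 was lost and 7 gained; with ranks 98 kept them, 10 were lost, 6 gained and 2 turned. Of named genes with a value, 271 of 283 stayed called or not called under quantile normalization and 12 called genes were lost; 268 of 284 stayed so with adjustment within each table and 16 called genes were lost, all in BZR1-YFP; a pseudocount of 0.1 moved 4 of 284 log2 values by more than their standard error, and a pseudocount of 1 moved 78. No paired analysis was possible because the tables hold 1 pooled value per group, although the labels share replicate numbers. For the same reason other count normalizations, other count tests, limma without trend, leave-one-out, a fit of fewer samples and an estimated correlation in camera were not run. Depth is unknown, so its limit could not be given.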

Other observations

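The families below were chosen after the data were seen: every symbol prefix with at least 10 tested members was tested in each comparison (140 families, 816 tests by one-sided Fisher's exact test for more calls than by chance, of which 34 passed after adjustment). With brassinolide 11 of 28 arabinogalactan protein genes (AGP) rose and 1 fell (adjusted p = 9.3e-08); AGP15 rose from 113 to 205 FPKM and AGP4 from 8.95 to 27.0 FPKM. Of the related fasciclin-like genes (FLA) 7 of 15 rose and 1 fell (adjusted p = 1.02e-05), FLA9 from 127 to 385 FPKM and FLA2 from 52.5 to 115 FPKM. Of 19 genes with a symbol that starts with PIP, which are plasma membrane aquaporins and PIP5K lipid kinases, 8 rose and 0 fell in the authors' deposited table (adjusted p = 4.24e-06); all that rose were aquaporins, among them PIP2A from 249 to 467 FPKM and PIP1B from 416 to 635 FPKM.

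In BEH2-YFP 15 of 38 genes with the symbol CRK, most of them cysteine-rich receptor-like kinases, rose and 4 fell (adjusted p = 3.61e-06), CRK5 from 3.05 to 7.53 FPKM and CRK11 from 7.12 to 17.5 FPKM. Of 28 beta-glucosidases (BGLU) 10 rose and 4 fell (adjusted p = 0.000838), BGLU45 from 2.13 to 55.6 FPKM, and of 39 UMAMIT transporters 9 rose and 0 fell (adjusted p = 0.04), UMAMIT29 from 9.10 to 21.2 FPKM. Of 18 nudix hydrolases (NUDT) 7 fell and 1 rose (adjusted p = 0.000457), NUDT4 from 15.8 to 5.84 FPKM. Chloroplast-encoded genes, of which 2 of 43 were called in BEH2-YFP, both lower, had a median log2 change of -0.58 in BZR1-YFP. There the median was -0.53 for snRNA genes and -0.84 for snoRNA genes, and the 1 rRNA locus tested fell (log2 -1.06), while the medians of lncRNA, antisense and miRNA genes lay above 0 in both lines. Genes outside the rule for named genes also stood out by size: AT3G01345 rose from 0.275 to 110 FPKM in BEH2-YFP and stood at 0.580 FPKM in BZR1-YFP. In BZR1-YFP the noncoding gene AT2G01422 fell from 30.4 to 0.356 FPKM and DML1, a DNA demethylase, fell from 15.9 to 7.44 FPKM. HR4 stood at 689 FPKM in Col-0 mock, 517 with brassinolide, 42.6 in Col-0, 338 in BEH2-YFP and 99.7 in BZR1-YFP.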
